A study of Mus musculus with 6 samples.

How the data were processed

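The series holds RNA sequencing of sorted lung ILC2s from 6 samples, 3 WT and 3 KO, each a pool of 3 to 4 mice, all after 4 days of IL-33. Per the labels, full-length cDNA was made with a SMART-Seq HT kit from RNA at 7 to 14 ng/ul, and libraries with a transposase-based TruePrep V2 kit. Per the submitters' processing notes, HISAT2, Cufflinks and mm10 were used, with no versions given. The counting tool, the annotation, the filters and the handling of strand are not given in the sources used here. A kit that does not mark strand cannot separate a gene from an overlapping antisense gene.

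The deposited table holds 39527 genes. Per the file headers, the authors gave for each gene a mean normalized count, a signal averaged over the libraries of their fit. Per the file headers, the authors also gave a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value. These column names are those of the results table of DESeq2, per the file headers, although no source used here states which tool the authors ran. The score equalled the log2 fold change divided by its standard error to within 2.4e-07, the p-value its 2-sided normal p to within 5.0e-08, and the adjusted p-value a Benjamini-Hochberg adjustment of the deposited p-values to within 7.6e-07. Adjusted p-values were present for 14961 genes, whose mean was at least 10.46 normalized counts, and absent for 24483 genes with a p-value, while 83 genes had no p-value. The hemoglobin genes Hba-a1 and Hbb-bs and the club cell gene Scgb1a1 were among the 83 and entered no test. Which libraries, and how many, lie behind the authors' fit is not given in the sources used here. The fit may hold libraries beyond the 6 samples, so that the p-values cannot be read as those of 3 samples against 3.

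A further 12 columns of per-sample values, under 6 names, matched no label; they were seen when the table was first inspected and entered no result. Every analysis planned on per-sample values was therefore replaced by one on the authors' comparison. The plan, fixed before the data were examined, had been a count or limma fit of KO against WT. The direction of the deposited fold change is not stated, so that signs are reported as deposited. The depth of each sample was not used here, and the precision of each value is that of its deposited standard error, with a median of 0.233 over tested genes, 0.145 in the most abundant 25% and 0.609 below 100 normalized counts. The 95% intervals are the fold change with its standard error under a normal distribution.

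Genes were called at an adjusted p below 0.05. Gene lists (32, of which 20 core and 12 control) were fixed before the data were examined. The 30 lists with at least 5 tested members were tested with the pre-ranked camera test of limma 3.58.1 in R 4.3.3, on the deposited score with an inter-gene correlation of 0.01, 2-sided, and adjusted by Benjamini-Hochberg over the 30 lists. The correlation could not be estimated without per-sample values, so that correlations of 0.05 and 0.1 were tried in its place. The sex-linked list (1 tested member, not called) and the erythroid list were too small to test. Counts over a list alone used a Benjamini-Hochberg adjustment of its members' p-values. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

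Named genes followed a rule fixed before the data were examined. It took Stk11, the 10 largest positive and 10 largest negative fold changes among called genes with a mean of at least 5 CPM, 3 members with the smallest p in each core list with a call (1 in a list without), and the most abundant and the most significant member of each control list. Predicted genes, pseudogenes, receptor segments, mitochondrial and sex-linked genes were left out of the largest changes. The rule also required complete separation of the samples, which could not be applied, and CPM was taken as the share of the summed mean normalized counts (17649719), so that 5 CPM stood for 88.2 normalized counts. Both adaptations were made after the columns were seen. List members named beyond the rule were chosen after their values were seen. Some genes that the rule selects are not reported here.

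Coordinates, gene lengths and GC content were taken from GENCODE M21 on the mm10 assembly, in which 39191 gene identifiers (99.15%) were found. Dates stood in place of 27 gene symbols, and these genes were matched by identifier. For the length and GC check, lowess trends on exonic length and then on GC content were removed from the fold changes of 13036 protein-coding genes.

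The call count was tested on simulated data with the deposited standard errors of 14961 genes and 200 changed genes. In 20 draws, 18.5% of genes changed by 0.5 on the log2 scale were recovered, 57.6% of those changed by 1 and 82.9% of those changed by 2, with 5.12% false calls. The list test called 98 of 100 simulated lists of 36 genes with each score shifted by -1 and 1 of 3000 lists without a shift. Simulated genes were independent of each other, so that these rates do not cover lists of correlated genes. Far fewer genes were changed than the 3668 called in the data. Recovery depends on that share, so that the recovered percentages need not hold for the data. Noise was drawn from the normal errors that the adjustment assumes, so that the rate of false calls checks the counting and not the deposited p-values. Alternatives covered the threshold, the genes adjusted over, the adjustment, the centring, the removal of length and GC trends, and for lists the correlation and the use of ranks.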

Results

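Gene expression was measured by RNA sequencing in group 2 innate lymphoid cells (ILC2s) sorted from mouse lung after 4 days of challenge with IL-33, the epithelial alarmin that activates these cells. The labels give 2 groups of 3 samples: R5/+ mice (WT) and R5/+ mice with floxed alleles of LKB1 (KO). LKB1, encoded by Stk11, is the serine/threonine kinase that activates AMPK and its relatives. Each sample was a pool of 3 to 4 mice, so that differences between single animals were averaged within a sample. The series title places the comparison in a study of ILC2 exhaustion and lung cancer metastasis. The values used were the authors' gene-level comparison of the genotypes, with 1 fold change and 1 standard error per gene, and the sequencing depth of single samples was not used here.

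Neither the column names nor the labels state which genotype was the numerator of the fold change. The labels name the comparison with WT before KO, and read as WT over KO this order would put Stk11, the gene floxed in KO, lower in WT, since its deposited fold change was negative. Deletion in KO would lower Stk11 there, so that its value of -1.34 ± 0.30 (SE) in the authors' deposited table argues against that reading. No source used here states the direction, and the inference rests on 1 gene. Fold changes are therefore given with the sign they carry in the table, called positive or negative, and no gene is assigned to the WT or the KO side.

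The deleted gene was measured first. Stk11 (ENSMUSG00000003068, mm10 chromosome 10, 80115803 to 80130682) had a log2 fold change of -1.34 ± 0.30 (SE) in the authors' deposited table, with a mean of 652.3 normalized counts and an adjusted p of 0.000102557. The value covers the whole gene, including exons outside the floxed part, which the labels do not describe. A negative sign below is the sign shared with Stk11. Where members of a list or group of genes are counted below, positive and negative mean an adjusted p below 0.05 with that sign.

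Of 14961 genes with an adjusted p, 3668 (24.5%) passed 0.05, 1644 with a positive and 2024 with a negative fold change. At least 2-fold differences were found for 526 of the positive and 616 of the negative genes. The median log2 fold change was -0.0056 over all genes with an adjusted p and -0.0373 over the most abundant 25% of them.

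**Figure D1:**
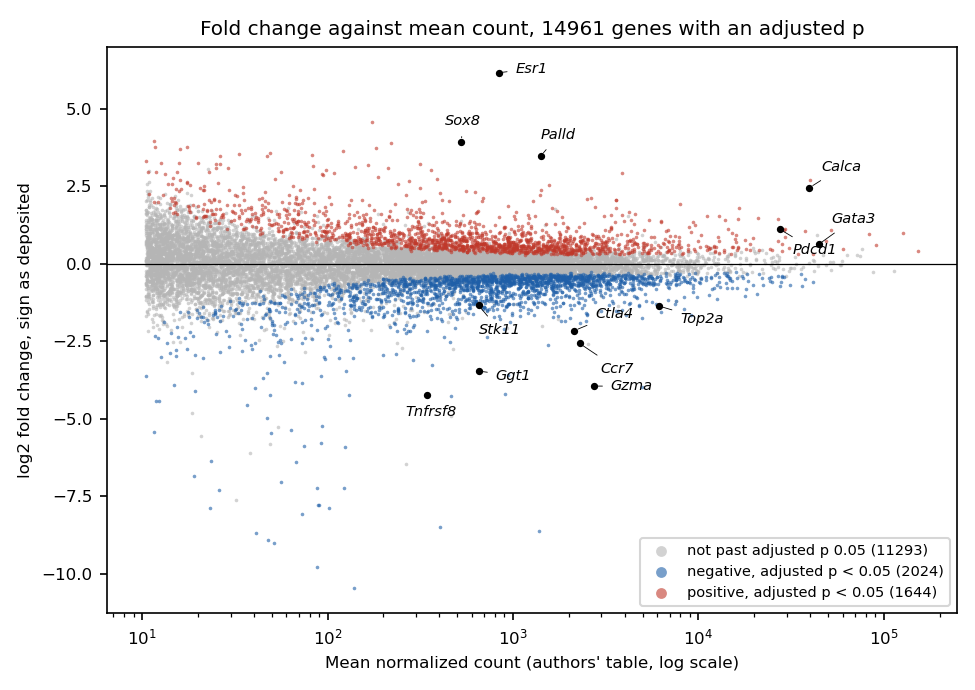
Log2 fold change (vertical axis, sign as deposited) against the mean normalized count (horizontal axis, log scale) for 14961 genes in the authors' deposited table, each point a gene. The 1644 positive and 2024 negative genes past an adjusted p of 0.05 are coloured, and Esr1 at 6.17 lies above every other named gene.

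Among the genes chosen by size of change, the largest positive value belonged to Esr1, the estrogen receptor alpha, at 6.17 ± 1.11 (SE) in the authors' deposited table. Sox8, a transcription factor of the SoxE group, stood at 3.94 ± 0.24 and Palld, the actin-binding protein palladin, at 3.48 ± 0.16 in the authors' deposited table. Palld had the smallest adjusted p of all genes, 3.05e-103 in the authors' deposited table. The Notch ligand Jag1 (3.24 ± 0.33), the potassium channel regulator Abcc8 (3.03 ± 0.30) and the lipid flippase Atp8a2 (3.91 ± 0.32) were also positive in the authors' deposited table. Edil3, Fa2h and Sema3a had log2 fold changes of 3.74, 3.65 and 3.19 in the authors' deposited table. The cytokine Il3 had 3.13 ± 1.19, a wide error with an adjusted p of 0.038225927 in the authors' deposited table.

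On the negative side stood Chia1, an acidic mammalian chitinase, at -4.25 ± 0.92, and Tnfrsf8, which encodes CD30, at -4.22 ± 0.75 in the authors' deposited table. Retnla, a resistin-like protein of type 2 inflammation, had -4.21 ± 1.11 and the granzyme gene Gzma -3.94 ± 0.93 in the authors' deposited table. Ggt1, a gamma-glutamyltransferase, had -3.46 ± 0.24 with an adjusted p of 9.55e-42 in the authors' deposited table. Cxcl13, Adap1 and Mmp10 had log2 fold changes of -3.60, -3.46 and -3.25 in the authors' deposited table. Jchain, the joining chain of secreted immunoglobulin, had -3.57 ± 1.37 in the authors' deposited table, and 34 of 52 tested immunoglobulin segments were negative with 0 positive. The standard errors of Chia1, Retnla, Gzma, Cxcl13 and Jchain, between 0.92 and 1.37, were wide beside the median of 0.233 over tested genes. The sizes of these changes are therefore uncertain, and whether 1 sample carries them was not tested. Dynlt1f (-3.08 ± 0.97 in the authors' deposited table) has near-identical paralogs that can share reads, so that its value is uncertain.

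**Figure D2:**
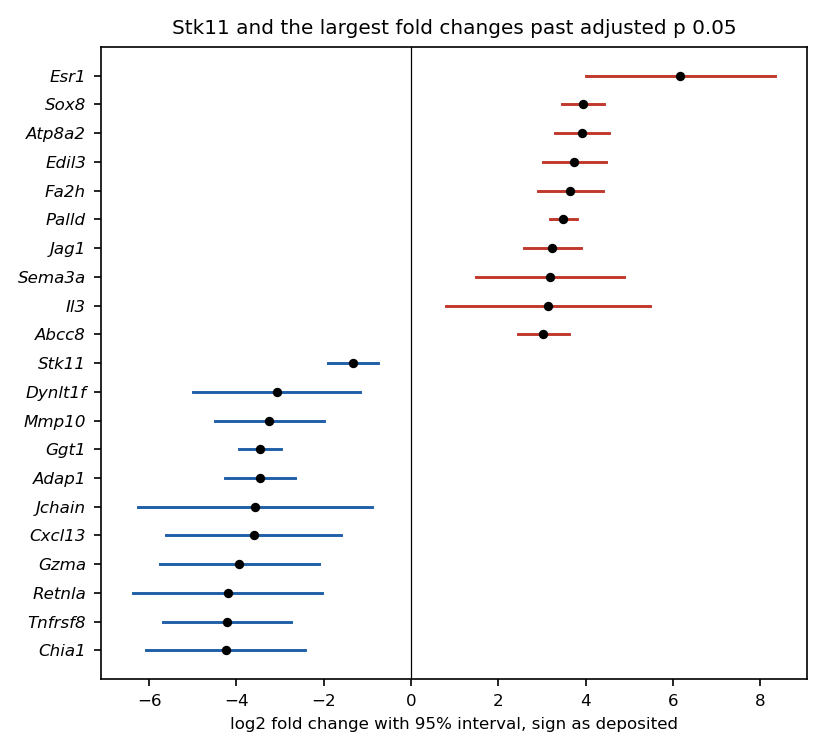
Log2 fold change (horizontal axis, sign as deposited) of Stk11 and of the 10 largest positive and 10 largest negative genes chosen by rule from the authors' deposited table. Points are the fold changes and bars the 95% intervals from the deposited standard errors, which are narrow for Palld (3.17 to 3.79) and wide for Esr1 (4.0 to 8.33).

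Genes of the cell cycle were mostly negative. Of 30 tested members, 27 were negative and 1 positive, with a median log2 fold change of -1.27 (camera adjusted p = 8.28e-21). Mitotic genes were among them, with Ccnb2 at -1.64 ± 0.20, Birc5 at -1.75 ± 0.24 and the topoisomerase Top2a at -1.36 ± 0.20 in the authors' deposited table. The replication helicase genes Mcm2 to Mcm7 were all negative, between -1.29 and -1.04 in the authors' deposited table. The positive exception was the D-type cyclin Ccnd2, at 0.85 ± 0.18 in the authors' deposited table. Ccnd3 (0.23) and E2f1 (0.02) did not pass in the authors' deposited table. The counts were the same when p was adjusted over the list alone.

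Nuclear genes of the respiratory chain lay below 0 in all 36 members, of which 27 were negative past the threshold and 0 positive. Their median was -0.548 (camera adjusted p = 2.92e-13). Adjusted over the list alone, 29 were negative. Ndufa4 had -0.90 ± 0.14 and the cytochrome c oxidase subunit Cox5b -0.73 ± 0.14 in the authors' deposited table. Of the 12 tested genes of the mitochondrial genome, 6 were negative and 0 positive (camera adjusted p = 0.00396), with mt-Cytb at -0.59 ± 0.11 in the authors' deposited table, and 7 were negative adjusted over the list alone. Fold changes also followed gene length, with a Spearman rho of 0.263 over 13036 protein-coding genes and a median log2 fold change of -0.244 in the shortest and 0.155 in the longest 25% of these genes. After removal of this trend and of that with GC content, the respiratory chain list had a median of -0.364 and kept its call (camera adjusted p = 4.04e-05), while the adjusted p of the mitochondrial genome list was 0.763. At an inter-gene correlation of 0.1 and with the trends kept, the adjusted p of the mitochondrial genome list was 0.0734.

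Of 24 antioxidant genes, 21 lay below 0 and 3 above. Past the threshold, 10 were negative and 0 positive (median -0.463, camera adjusted p = 0.000162), or 12 negative adjusted over the list alone. They included the peroxiredoxin Prdx1 (-1.16 ± 0.18), the thioredoxin Txn1 (-0.77 ± 0.13) and the transketolase Tkt (-0.80 ± 0.15) in the authors' deposited table. Of 29 genes of fatty acid and sterol synthesis, 25 lay below 0 and 4 above. Past the threshold, 9 were negative and 1 positive (median -0.318, camera adjusted p = 0.0049), the same counts as adjusted over the list alone. The sterol enzymes Idi1, Sqle and Cyp51 had -0.998, -0.72 and -0.62 in the authors' deposited table, and the positive member past the threshold was the elongase Elovl5 (0.47). After removal of the length and GC trends the antioxidant median was -0.267 (camera adjusted p = 0.00509). With the trends kept, the adjusted p was 0.062 for the antioxidant list at a correlation of 0.1, and 0.0746 for the synthesis list at 0.05.

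ILC2 identity genes were positive in 12 and negative in 5 of 25 members, with a median of 0.378 (camera adjusted p = 0.00725), and 14 were positive adjusted over the list alone. The receptor tyrosine kinase Kit had 1.53 ± 0.16, the TSLP receptor gene Crlf2 0.90 ± 0.14 and the Notch target Hes1 1.10 ± 0.23 in the authors' deposited table. Gata3, the ILC2 lineage factor, had 0.63 ± 0.16 in the authors' deposited table. The negative members were Tcf7, Tnfrsf4, Arg1, Klrg1 and Thy1, between -1.98 and -0.44 in the authors' deposited table. The adjusted p of the list was 0.0746 at a correlation of 0.05 and 0.229 at 0.1. Markers of other cell types had fold changes of the opposite sign, below 0 in 86 of 103 tested members.

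Immediate early and heat shock genes, which also respond to cell handling, were positive in 11 of 18 members and negative in 0 (median 0.712, camera adjusted p = 1.38e-09), or 15 adjusted over the list alone. Jun had 1.45 ± 0.16 in the authors' deposited table, while Junb, the most abundant member, had 0.48 ± 0.20 with an adjusted p of 0.064247393. Interferon response genes were positive in 8 and negative in 2 of 24 members (median 0.368, camera adjusted p = 0.0231), also when adjusted over the list alone. The deubiquitinase-like Usp18 had 1.62 ± 0.22 and Rtp4 1.58 ± 0.29, against -1.92 ± 0.34 for Ifi27l2a in the authors' deposited table. The interferon list had an adjusted p of 0.137 at a correlation of 0.05 and of 0.0524 on ranks.

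**Figure D3:**
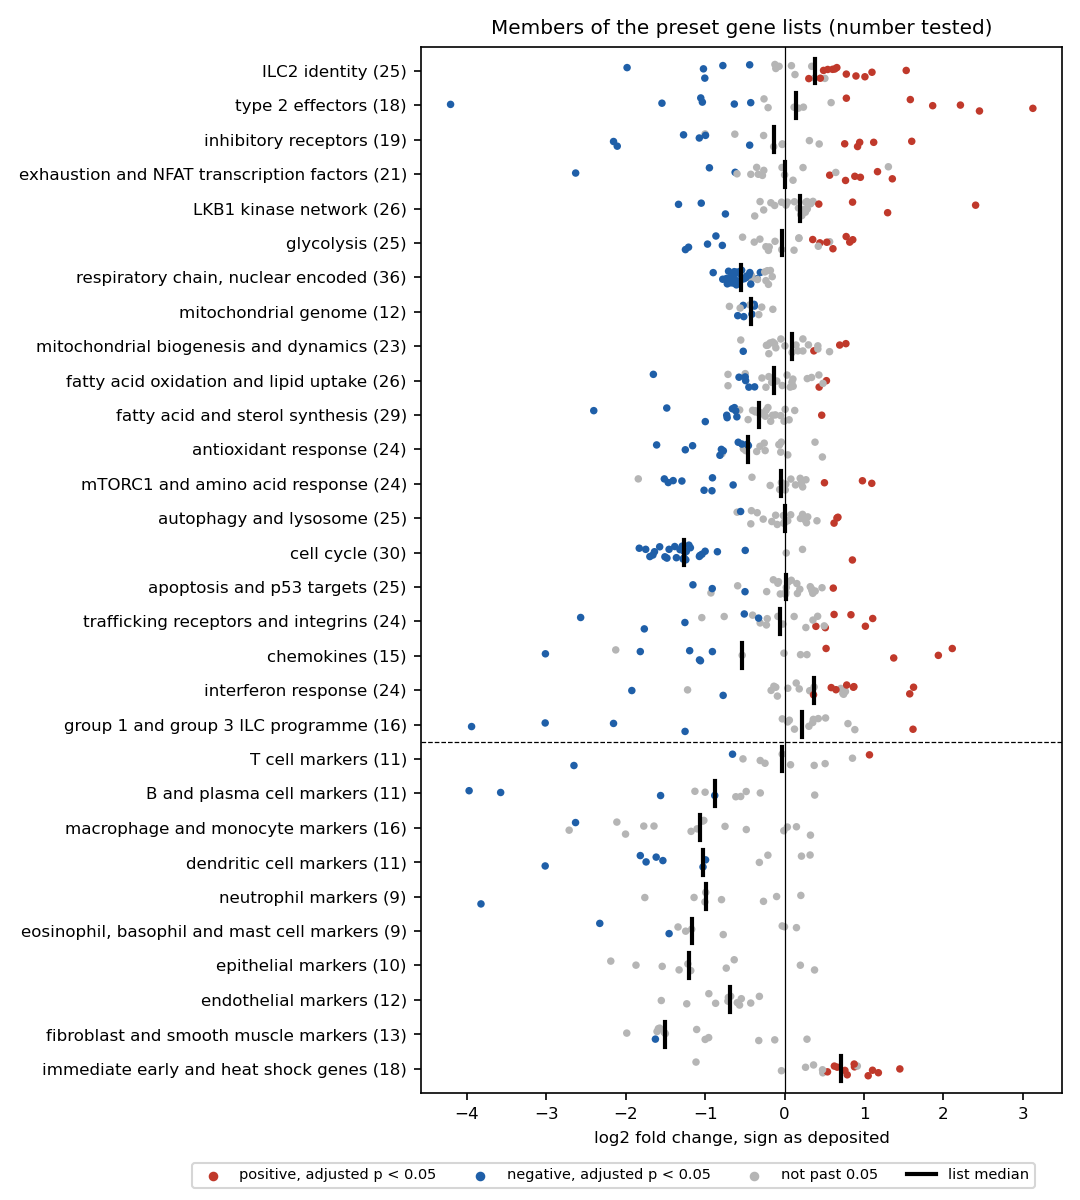
Log2 fold change (horizontal axis, sign as deposited) of each tested member of the preset gene lists with at least 5 tested members, from the authors' deposited table, with core lists above and control lists below the dashed line and the number tested in brackets. Points are genes, coloured where the adjusted p is below 0.05, and black bars are list medians, which run from -1.50 for fibroblast and smooth muscle markers to 0.712 for immediate early and heat shock genes.

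Inhibitory receptors, the group closest to the exhaustion named in the title, went both ways. Of 19 tested members, 5 were positive and 6 negative, and the list did not pass (camera adjusted p = 0.831). The preset list also holds genes that are not inhibitory receptors, among them Tnfrsf9 and the ectoenzyme Nt5e, both counted as positive. Pdcd1, which encodes PD-1, had 1.12 ± 0.18 and the costimulatory receptor Tnfrsf9 1.60 ± 0.18 in the authors' deposited table. Nt5e, Lilrb4a and Cd200r1 were positive too, between 0.76 and 0.95 in the authors' deposited table. Against these, Ctla4 had -2.15 ± 0.26 and Cd160 -2.11 ± 0.32 in the authors' deposited table. Tigit, Vsir, Cd244 and Klrg1 were negative as well, between -1.27 and -0.44 in the authors' deposited table. Lag3 (-1.001) and Havcr2 (0.44) did not pass in the authors' deposited table.

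Transcription factors tied to exhaustion and NFAT signalling were positive in 6 and negative in 3 of 21 members (camera adjusted p = 0.78). Tox and Tox2, which are related HMG-box factors, had opposite signs, 0.77 ± 0.12 and -2.63 ± 0.25 in the authors' deposited table. The orphan receptor Nr4a1 had 0.95 ± 0.19, and Nr4a2 and Nr4a3 were positive at 1.17 and 1.36 in the authors' deposited table. Batf and Irf4 were negative at -0.62 and -0.95 in the authors' deposited table.

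Type 2 effectors were positive in 6 and negative in 6 of 18 members (camera adjusted p = 0.419), or 7 and 6 adjusted over the list alone. Calca, which encodes the neuropeptide CGRP, had 2.45 ± 0.24 at a mean of 39616 normalized counts, and the cytokine Lif 1.58 ± 0.23 in the authors' deposited table. Il13 had -1.06 ± 0.18 and Il10 -1.54 ± 0.29, while Il4 had 0.78 ± 0.24 in the authors' deposited table. Il5 had 0.12 and did not pass in the authors' deposited table.

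In the LKB1 kinase network, 4 members were positive and 3, Stk11 included, negative of 26 (camera adjusted p = 0.378). Prkaa2, an AMPK catalytic subunit, had 2.41 ± 0.34 and the related kinase Nuak2 1.30 ± 0.18, and the AMPK subunit Prkag2 had -1.05 ± 0.18 in the authors' deposited table. Prkaa1, the other catalytic subunit, had 0.20 and did not pass in the authors' deposited table. Glycolysis genes were positive in 7 and negative in 5 of 25 members (camera adjusted p = 0.812). Tpi1, Pgk1 and the lactate transporter Slc16a1 were negative at -1.25, -0.97 and -1.21 in the authors' deposited table, and Hk2 and Pfkm positive at 0.86 and 0.78.

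Genes of mTORC1 and the amino acid response were positive in 3 and negative in 8 of 24 members (camera adjusted p = 0.213). The serine and one-carbon enzymes Phgdh and Mthfd2 had -1.46 ± 0.24 and -1.40 ± 0.17, the asparagine synthetase Asns -1.51 ± 0.24 and the mTORC1 subunit Rptor 0.98 ± 0.15 in the authors' deposited table. Fatty acid oxidation and lipid uptake genes were positive in 2 and negative in 6 of 26 members (camera adjusted p = 0.289), with Fabp5 at -1.65 ± 0.19, Acadl at -0.50 ± 0.11 and Hadh at -0.57 ± 0.14 in the authors' deposited table. Mitochondrial biogenesis and dynamics genes were positive in 3 and negative in 1 of 23 (camera adjusted p = 0.544), with Polg at 0.69, Ppargc1b at 0.77 and Tfam at -0.52 in the authors' deposited table. Autophagy and lysosome genes were positive in 3 and negative in 1 of 25 (camera adjusted p = 0.444), with Mcoln1 at 0.66, Tfeb at 0.67 and Ctsl at 0.62 in the authors' deposited table. Apoptosis and p53 target genes were positive in 1 and negative in 3 of 25 (camera adjusted p = 0.86), with Pmaip1 at -0.91 and Cdkn1a at 0.61 in the authors' deposited table. Adjusted over the list alone, the counts were 3 and 9 for the amino acid response, 3 and 6 for fatty acid oxidation, 2 and 1 for mitochondrial biogenesis and 1 and 2 for apoptosis genes. The median of the apoptosis list was 0.022 while its mean was -0.046 and its test negative.

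Trafficking receptors and integrins were positive in 6 and negative in 5 of 24 members (camera adjusted p = 0.544). The lymph node homing receptor Ccr7 had -2.57 ± 0.21 and the egress receptor S1pr1 -1.25 ± 0.24, while Cxcr4 had 1.02 ± 0.26 in the authors' deposited table. Chemokines were positive in 4 and negative in 6 of 15 (camera adjusted p = 0.378), with Cxcl2 at 1.94 ± 0.25, Ccl24 at -3.01 ± 0.34 and Cxcl10 at -0.91 ± 0.16 in the authors' deposited table. Of 16 members of the group 1 and group 3 ILC programme, 11 lay above 0 and 5 below. Past the threshold, 1 was positive and 4 negative (camera adjusted p = 0.926), with Gzmb at -2.15 ± 0.32 and Klrk1 at 1.62 ± 0.31 in the authors' deposited table. The median of this programme was 0.216 while its mean was -0.306 and its test negative.

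Markers of other cell types were measured as controls. Dendritic cell markers were negative in 7 of 11 members and positive in 0 (median -1.03, camera adjusted p = 0.000162). They included the MHC class II genes H2-Ab1 (-1.74 ± 0.22) and Cd74 (-0.99 ± 0.21) in the authors' deposited table. Both genes are also expressed by activated ILC2s. B and plasma cell markers were negative in 4 of 11 (camera adjusted p = 0.179), with Ighm at -1.56 ± 0.53 and Cd79b at -0.88 ± 0.23 in the authors' deposited table. Macrophage and monocyte (1 of 16), neutrophil (1 of 9), eosinophil, basophil and mast cell (2 of 9) and fibroblast and smooth muscle markers (1 of 13) had few members past the threshold, all negative. Their camera adjusted p values were 0.213, 0.419, 0.378 and 0.213. Most of their members lay below 0 (13, 8, 8 and 12 in this order). Among these, C1qa had -2.63 ± 0.78, Ngp -3.82 ± 1.35, Ccr3 -1.45 ± 0.38 and Pdgfrb -1.63 ± 0.34 in the authors' deposited table. Of epithelial and endothelial markers, 0 of 10 and 0 of 12 passed (camera adjusted p = 0.378 and 0.383), with Sftpc at -1.18 ± 0.84 and Pecam1 at -0.32 ± 0.17 in the authors' deposited table. The most abundant macrophage, neutrophil, mast cell and fibroblast markers, Lyz2 (-0.75), S100a8 (-1.14), Cpa3 (-0.03) and Fn1 (0.28), did not pass in the authors' deposited table. T cell markers were positive in 1 and negative in 2 of 11 (camera adjusted p = 0.419), with Trat1 at -2.65 ± 0.35 and Cd3g at -0.66 ± 0.19 in the authors' deposited table. Of the erythroid markers, 2 were tested and 0 passed, with Slc4a1 at 3.08 ± 1.64 in the authors' deposited table. Over all 10 lists of other cell types, 86 of 103 tested markers had a fold change below 0, 18 of them past the threshold, Jchain among these. Adjusted over the list alone, the counts of all lists not given so above were the same as over all genes.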

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

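All alternatives except the 2 thresholds were chosen after the data were seen. Requiring an absolute log2 fold change of at least 1 gave 526 positive and 616 negative genes, and the Benjamini-Yekutieli adjustment gave 845 and 1163, both by construction stricter. Under the other alternatives the counts stayed within 1.5 times, from 1264 to 2081 positive and 1498 to 2438 negative genes. The positive share of calls moved from 44.8% to 50.8% when centred on the most abundant 25% of genes and to 49.5% with length and GC trends removed. Stk11 stayed negative and past the threshold in each. Of 98 named protein-coding genes, 6 were lost with length and GC trends removed (Jchain, mt-Cytb, mt-Nd4, mt-Nd1, Tfam and Acadl), against 30 of 100 under the fold threshold, 10 under Benjamini-Yekutieli and 3 adjusted over every p. No called named gene changed sign under these alternatives. Positive lists past the threshold numbered 1 at a correlation of 0.05 and 1 at 0.1, and negative lists numbered 3 at 0.1, where the cell cycle, respiratory chain and dendritic cell lists remained, since a larger assumed correlation widens the error.

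No paired analysis was possible because the per-sample columns matched no label. For the same reason leaving out each replicate, other normalizations and filters, other splits of the samples, an estimated correlation and fry were not run, so that whether 1 sample carries a call was not tested. Below 100 normalized counts the median standard error of 0.609 limits calls to large changes.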

Other observations

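The tests on other cell types, the intron test with exonic length held, the low-count test and the 6 gene families were chosen after related results had been seen. The list medians and the counts of calls by gene type were also known when the remaining tests were set.

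In 6 gene families defined by symbol, of ribosomal proteins, proteasome and chaperonin subunits, synthetases and initiation factors, the called genes were all negative, while some uncalled members lay above 0. Among 77 cytosolic ribosomal protein genes 46 were negative and 0 positive (median log2 fold change -0.378), with Rps2 at -1.03 ± 0.13 (SE) in the authors' deposited table. Mitochondrial ribosomal proteins were negative in 45 of 76 (median -0.498), and proteasome subunits in 26 of 37 (median -0.50), with 0 positive in both. Cytosolic chaperonin subunits were negative in 6 of 7, aminoacyl-tRNA synthetases in 10 of 18 and eukaryotic initiation factors, with their binding proteins, in 22 of 48, again with 0 positive. All 6 families passed the camera test, with adjusted p values over the 6 between 4.92e-14 and 0.000317. The families were chosen after these data were seen and tested on the same fold changes. These p values and those below therefore describe the families and are not independent support. With length and GC trends removed the medians shrank, to -0.174 for cytosolic and -0.299 for mitochondrial ribosomal proteins and -0.32 for proteasome subunits, and little for synthetases (-0.456 to -0.429), and adjusted p values lay between 1.65e-06 and 0.0012. At a correlation of 0.1 and with the trends kept, the adjusted p values lay between 0.00129 and 0.0181. Removal of the trends together with that correlation was not run. Ribosomal protein genes have many processed pseudogenes that can share reads, so that their values are uncertain.

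The respiratory chain list was negative, with a median of -0.548, and its members are short, with a median exonic length of 2124 bases against 4586 over 13036 protein-coding genes. With length and GC trends removed the median was -0.364, so that part of the shift went with those trends. The list still passed the list test at the assumed inter-gene correlation of 0.01 (camera adjusted p = 4.04e-05). At that correlation the result argues against length and GC bias as the whole cause. Removal of the trends together with a larger correlation was not run, so that this bias is not excluded there. With a trend on mean count removed the median was -0.51. The genotype stays open as a hypothesis, as does a difference between samples that the comparison columns cannot show.

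Markers of other cell types mostly had fold changes below 0. Over the 10 preset lists this held for 83.5% of 103 tested markers, above the highest of 10000 random lists matched on mean count (68.9%), although only 18 were called negative and 1 positive, and the dendritic cell list alone passed its test. With length and GC trends removed, medians shrank (macrophage and monocyte markers from -1.066 to -0.698). Still, 78.0% of 100 protein-coding markers lay below 0, against at most 69.0% in matched random lists. Removing those trends therefore left most markers below 0. Genes of the random lists were drawn independently, while markers of 1 cell type can vary together. Both comparisons with random lists can therefore overstate how unusual the shares were. The samples were sorted ILC2s, from which a sort should remove such cells. Fewer cells left over from it in the samples on the positive side could give these values. Whether 1 sample carries them could not be tested. Some abundant markers had wide standard errors, 0.84 for Sftpc at 7594.2 and 0.80 for Lyz2 at 4468.9 normalized counts. The median was 0.145 in the most abundant 25% of genes, and Cd74 had 0.21. Of the erythroid genes, 2 were tested and 0 passed, and Hba-a1 (1.87 ± 0.78 (SE)), Hba-a2 (1.04 ± 1.2), Hbb-bs (1.64 ± 0.92) and Hbb-bt (1.69 ± 0.89) in the authors' deposited table had no p-value. Whether the other types shared 1 common shift cannot be told apart from unequal shifts, since the 10 lists differed (Kruskal-Wallis permutation p = 0.0243, 100000 permutations), while the 8 lists without T cell markers, which ILC2s share, and without the erythroid list, of which only 2 genes of low abundance were tested, gave 88.9% and a permutation p of 0.8797, a set first chosen after the medians were seen. A change within the ILC2s of genes such as H2-Ab1 remains open.

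Unspliced and antisense transcripts (annotated as antisense, sense intronic or to be experimentally tested) were positive in 70 and negative in 5 of 680. Their median log2 fold change of 0.412 lay above protein-coding genes matched on mean count (-0.051 to 0.097), which argues against low counts. Over 594 pairs of a transcript and its overlapping protein-coding gene, the median difference in log2 fold change was 0.306 (95% bootstrap interval 0.25 to 0.375, resampling the 484 overlapping genes), which argues against the change of that gene as the whole cause. Across 12689 protein-coding genes with introns, which are not independent replicates, fold change rose with intron length (rho = 0.185), as more intronic reads could give. With exonic length held the correlation was 0.038, while exonic length itself had a rho of 0.265. Most of the trend with intron length therefore went with exonic length. What remained was too small to decide whether intronic reads add to it, and no biological explanation was tested.

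Strain DNA linked to the floxed allele was tested as a hypothesis by the calls within 5 Mb of Stk11, where 51 of 179 genes (28.5%) passed against 24.5% elsewhere (1-sided Fisher's exact p = 0.125), which leaves it open. Of the 51 calls, 39 were negative and 12 positive, against 55.2% negative over all calls, a difference that was not tested.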
